A study of Homo sapiens with 20 samples.

How the data were processed

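RNA-seq counts were available for 12 libraries of MCF-7 cells in 4 groups of 3: control siRNA or SET siRNA, each with ethanol vehicle or E2. Per the labels' protocols, cells stayed in phenol-red-free medium for 2 hours and were then grown for at least 72 hours with 5% hormone-stripped serum, and pools of siRNAs were transfected. Libraries were made from 1 µg of total RNA with a strand-keeping kit, per the labels. The deposited table holds whole-number counts per gene and library, not normalized, for 58336 Ensembl gene identifiers, as the authors made it. Per the submitters' processing notes, the tools were Bowtie2 2.3.4, SAMtools 1.7, MACS2 2.1.1, with the human build GRCh37 (hg19); the notes do not tie them to the RNA-seq or the ChIP-seq samples. The aligner and counting program of the RNA-seq, the gene annotation and the strand setting are not given in the sources used here. Antisense and overlapping genes, and genes with near-identical copies, are therefore uncertain. The 8 ChIP-seq samples were not analysed here. No reference genome was used, so no coordinates are given and no check of GC content or gene length was made.

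Columns of the table were matched to groups by the siRNA and treatment in their names. Replicates carry the letters A, B and C, which no label ties to the replicate numbers. Symbols were found for 41885 identifiers, 71.8% of the table, and older symbols in the gene lists were matched through their synonyms, which left 4 list genes without a match. Totals per library ran from 8865672 to 12653649 counts, and 24011 genes had no count in any library. Replicates of a group were compared by a chi-square test of their counts over genes with at least 20 counts. No pair held identical values, and the chi-square per degree of freedom ran from 1.27 to 4.57, where counting noise alone gives 1. The pairs that stood furthest apart held siSET E2 library A (4.15 and 4.57) and siSET vehicle libraries A and B (3.69).

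Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with its defaults, a count minimum of 10 and a total of 15, which left 16169 genes and removed 42167. Libraries were scaled by TMM, whose factors lay between 0.93 and 0.965 for siSET E2 libraries and between 1.005 and 1.035 for all others. One quasi-likelihood model was fitted over the 12 libraries with a mean per group and no covariate, so that all groups share one estimate of the spread; the common dispersion was 0.00124, a biological coefficient of variation of 3.52%. Each comparison was a contrast of that model, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The comparisons were the E2 effect with each siRNA, the knockdown effect with each treatment, and the difference between both E2 effects. All adjusted p-values per gene are from edgeR unless DESeq2 or limma-voom is named. The SE of a log2 fold change was its absolute value divided by the square root of the F statistic. CPM values use the TMM-scaled library size unless library size is named, with mean and SD over the 3 libraries of a group. Intervals and tests cover the spread between these libraries.

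The comparisons, their design, 20 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Genes were named if they were SET, ESR1, GREB1, TFF1, PGR, MYC or CCND1. They were also named if they were among the 8 largest rises or 8 largest falls of the first 3 comparisons (5 and 5 for the E2 effect in siSET cells and for the difference) with an adjusted p under 0.05, a mean log2 CPM of at least 3 and no overlap between libraries. Up to 4 members with the smallest p were taken from each list. Lists were tested with camera at its preset correlation of 0.01, with adjustment over the 20 lists of a comparison, and again with an estimated correlation; fry tested whether the genes of a set moved one way on balance. For the sets taken from the average E2 effect, fry and camera p-values were adjusted over the 4 sets, and those of alternative settings were not adjusted. Members were counted as called over all genes and adjusted over the list alone.

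The steps were tested on simulated data with genes changed by a known fold, 50 at each fold. For the E2 effect in siCtrl cells, over 15890 genes, 58% of the genes changed 1.2-fold, 80% at 1.5-fold, 92% at 2-fold and 98% at 4-fold were recovered. For the difference in E2 effect the shares were 34%, 60%, 82% and 96%. Among the calls were 13 and 9 unchanged genes, 7.3% and 6.2% of all calls, above the 5% that the threshold allows on average. A simulated comparison with no change gave 0 calls for the SET knockdown effect in vehicle. The simulation changed few genes, each with a mean of at least 1 CPM. In the data far more genes were called, 58.5% for the E2 effect in siCtrl cells, so the recovered shares need not hold there.

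Alternatives tried were RLE size factors, library size alone, mitochondrial, histone and ribosomal RNA genes left out, no low-count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust empirical Bayes, a fit over the 2 compared groups only, and each library left out in turn. A replicate block by column letter and a fit without siSET E2 library A and siSET vehicle library B were added after the data were examined. The labels name no batch. Figures were drawn with matplotlib in Python.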

Results

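The study profiled MCF-7 cells, an established luminal breast cancer line that carries estrogen receptor alpha, after knockdown of the SET oncoprotein. SET is a histone-binding protein and an inhibitor of the phosphatase PP2A. Cells were given a control siRNA (siCtrl) or a pool of siRNAs against SET (siSET), and then the ethanol vehicle or estrogen (E2). These 4 groups held 3 RNA-seq libraries each, 12 in all, and are the subject of the comparisons below. The labels give neither the dose nor the duration of E2 for these libraries. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The other 8 samples of the series are ChIP-seq samples and were not analysed here. The libraries held from 8865672 to 12653649 counts, and 16169 genes had enough counts to be tested. The first principal component, with 60.5% of the variance, separated E2 from vehicle, and the second, with 16.2%, separated the siRNAs.

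SET itself was measured first, as a check of the labels. In vehicle it stood at 565.3 ± 10.5 CPM (SD, n = 3) with control siRNA and at 145.5 ± 4.38 CPM (SD, n = 3) with SET siRNA. In E2 the values were 734.4 ± 7.6 CPM (SD, n = 3) and 190.1 ± 6.26 CPM (SD, n = 3). The knockdown left 25.7% of the transcript in vehicle and 25.9% in E2. The 6 siSET libraries lay between 140.9 and 196.9 CPM and the 6 siCtrl libraries between 554.4 and 743.1 CPM. Reads assigned to SET pseudogenes numbered 10 to 28 per library, too few to alter these values. SET also rose with E2, by 0.38 on the log2 scale with control siRNA (SE 0.04, adjusted p = 1.07e-11, edgeR) and by 0.39 with SET siRNA (SE 0.04, adjusted p = 2.17e-10, edgeR).

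**Figure D1:**
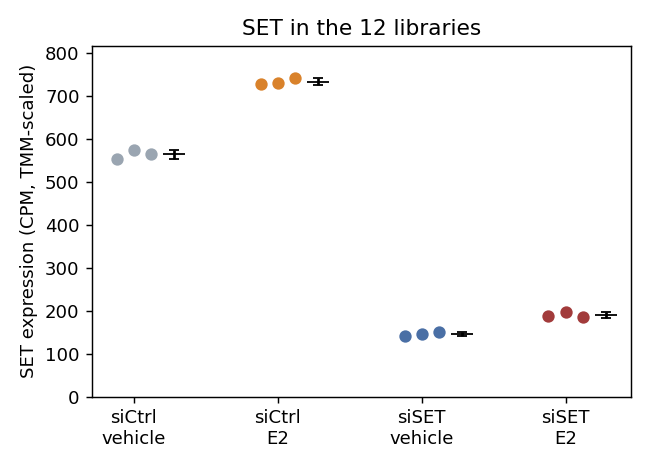
SET expression in CPM (vertical axis) in each of the 12 libraries, by siRNA and treatment (horizontal axis). Points are libraries and the line with bars is the mean with its SD over 3 libraries; the siSET libraries lie at or below 196.9 CPM and the siCtrl libraries at or above 554.4 CPM.

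The first comparison asked what estrogen changed in cells given the control siRNA. E2 raised estrogen receptor target genes together with genes of DNA replication, mitosis and ribosome biogenesis. TFF1, a secreted trefoil peptide, rose from 26.75 ± 3.51 to 349.9 ± 13.6 CPM (SD, n = 3). GREB1, a cofactor of the estrogen receptor, rose from 319.8 ± 10.0 to 1841 ± 29.6 CPM (SD, n = 3), 5.76-fold. PGR, the progesterone receptor, rose from 49.63 ± 3.32 to 356.5 ± 9.48 CPM (SD, n = 3), and ESR1, the estrogen receptor gene, fell from 1381 ± 19.9 to 795.2 ± 11.9 CPM (SD, n = 3).

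By edgeR, 9464 genes passed an adjusted p of 0.05, of which 4968 rose and 4496 fell, with 750 of the rises and 1055 of the falls at least 2-fold. Among all 16169 genes tested, the libraries of both groups did not overlap for 10303, where chance gives this for 10% of genes at 3 against 3. The genes with the largest rises by log2 fold change were the immediate early transcription factor EGR3 (5.81), TFF1 (3.70), MYBL1 (3.68), the Src-family kinase HCK (3.41), RAPGEFL1 (3.13), DOK7 (2.90), PGR (2.85) and MIR503HG (2.76). The largest falls were in the lectin gene CLEC3A (-6.86), WNT2B (-4.34), FSTL5 (-3.90), the forkhead factor FOXI1 (-3.85), the interleukin-1 receptor gene IL1R1 (-3.74), IFI44L (-3.67), HNRNPA1P41 (-3.45) and PMP22 (-3.25). HNRNPA1P41 is a pseudogene, for which reads of related genes can be miscounted, and its level varied widely within groups, at 14.93 ± 7.36 CPM in vehicle (SD, n = 3). CLEC3A was left at 0.29 ± 0.055 CPM with E2 (SD, n = 3). MYC rose by 1.06 and CCND1, the gene of cyclin D1, by 0.41, with SEs of 0.05 and 0.04.

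Of 54 estrogen-induced genes named before the data were examined, 49 rose and 2 fell (camera adjusted p = 3.91e-80); MYBL1, CELSR2, GREB1 and TFF1 had the smallest p. Of 20 estrogen-repressed genes, 16 fell and 2 rose (adjusted p = 9.22e-19), among them the apoptosis genes BMF (-3.03) and TP53INP1 (-2.12) and the receptor tyrosine kinase ERBB2 (-1.27). All 40 mitosis genes rose, with a median of 1.68 (adjusted p = 1.17e-111) and TOP2A (1.88), CENPF (2.06), AURKA (2.07) and PLK1 (2.05) as examples. Of 40 S phase genes, 38 rose and 1 fell, with a median of 0.70 (adjusted p = 4.67e-18), including TYMS (0.91) and TK1 (1.07). Of 32 ribosome biogenesis and MYC target genes, 31 rose, nucleolin (NCL, 0.75) and TCOF1 (1.12) among them (adjusted p = 1.79e-13). Histone chaperones rose in 20 of 25 cases and fell in 2 (adjusted p = 2.69e-06), and partners of SET and PP2A rose in 13 of 21 and fell in 2 (adjusted p = 6.5e-05). Their leading members were HMGB2 (1.48), ANP32E (1.11) and HJURP (1.62). Immediate early genes rose in 16 of 23 cases and fell in 4 (adjusted p = 0.000349), and p53 target genes fell in 13 of 26 and rose in 5 (adjusted p = 0.000159), including BTG2 (-3.03) and the cell cycle inhibitor CDKN1A (-1.13). Each of these lists also passed with an estimated correlation. Adjusted over the list alone, the estrogen-induced list held 52 called genes in place of 51, and the other lists of this paragraph had the same counts as over all genes.

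Calls on 3 further lists were lost with an estimated correlation. Of 34 interferon-stimulated genes, 31 fell and 1 rose, with a median of -1.06 (camera adjusted p = 4.26e-14, and adjusted p = 0.117 with an estimated correlation); BST2 (-1.93), IFIT1 (-2.36) and ISG15 (-1.34) were among them. Cholesterol synthesis genes rose in 18 of 24 cases and fell in 4 (adjusted p = 4.67e-06, and adjusted p = 0.0933 with an estimated correlation), with SQLE (0.85), LDLR (0.85) and DHCR7 (0.89) higher. Unfolded protein response genes rose in 14 of 24 cases and fell in 4 (adjusted p = 0.00413, and adjusted p = 0.0629 with an estimated correlation), including XBP1 (0.79). When adjusted over the list alone, 33 in place of 32 interferon-stimulated genes were called.

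The other 8 lists did not pass as sets. They were estrogen receptor and cofactors (9 rose, 13 fell of 27), histone acetylation and methylation enzymes (14 rose, 11 fell of 34), and hypoxia and glycolysis genes (9 rose, 9 fell of 23). Replication-dependent histone genes gave 12 rises and 9 falls of 23, and mitochondrially encoded genes 1 rise and 3 falls of 13. Among markers of cell types, luminal epithelial genes rose in 6 and fell in 10 of 18 cases, basal and mesenchymal genes rose in 6 and fell in 4 of 14, and fibroblast, endothelial and immune genes rose in 3 and fell in 2 of 6 measured. Camera's direction was opposite in sign to the median for the histone enzyme, luminal, basal and histone gene lists, whose medians were 0.06, -0.14, 0.19 and 0.44 and whose means were -0.02, 0.25, -0.08 and 0.19. Adjusted over the list alone, the called genes numbered 23 for the cofactors, 27 for the histone enzymes, 19 for the hypoxia list, 17 for the luminal list and 1 for the mitochondrial list, against 22, 25, 18, 16 and 4 over all genes.

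**Figure D2:**
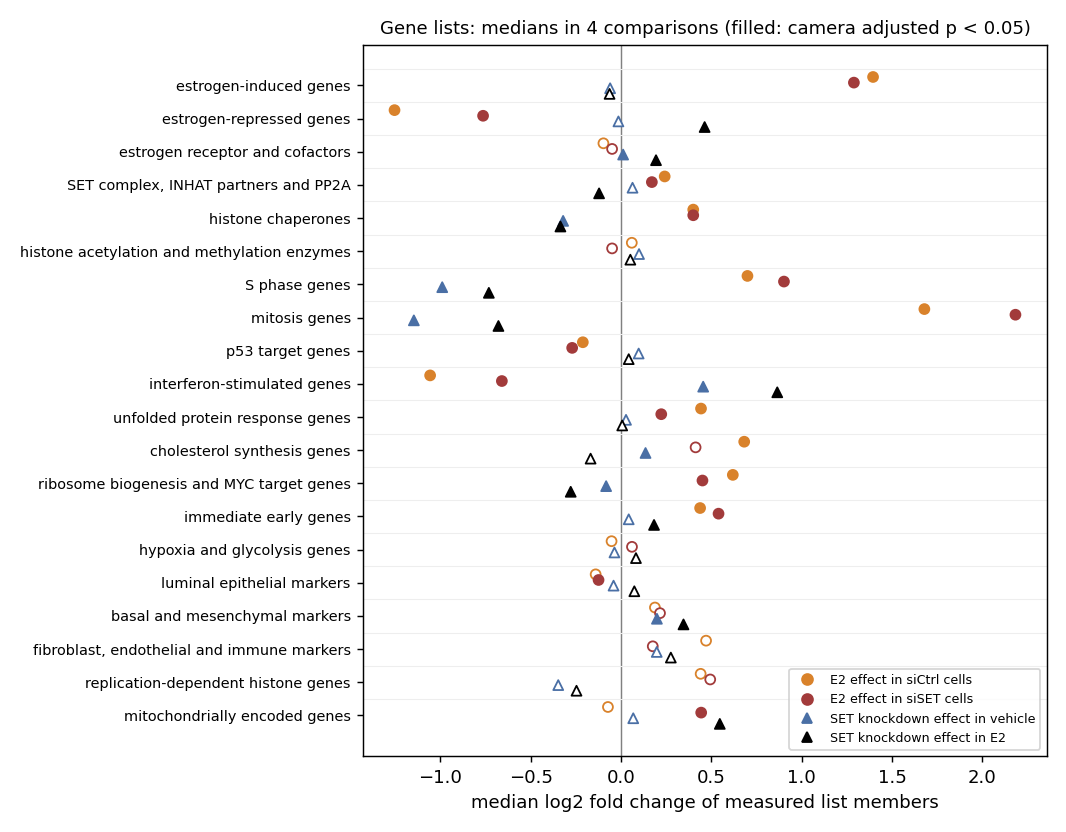
Median log2 fold change over the measured members of each gene list (horizontal axis) for both E2 effects (circles) and both SET knockdown effects (triangles), one row per list. Filled symbols passed camera at an adjusted p under 0.05; the mitosis list has medians of 1.68 and 2.18 for E2 and of -1.15 and -0.68 for the knockdown.

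The comparison of SET siRNA with control siRNA in vehicle addressed what the SET siRNA pool changed without estrogen. No group holds a different SET siRNA or restored SET. Loss of SET and other effects of the pool can therefore not be told apart. Cell cycle genes fell together: TOP2A, a topoisomerase of dividing cells, dropped from 226.9 ± 13.2 to 94.23 ± 2.02 CPM (SD, n = 3), and RRM2, a ribonucleotide reductase subunit, from 171.5 ± 4.45 to 67.54 ± 0.412 CPM (SD, n = 3). Nucleolin fell from 504.6 ± 22.0 to 190.3 ± 3.39 CPM (SD, n = 3). Fibronectin (FN1) rose from 132.0 ± 2.66 to 292.0 ± 6.25 CPM (SD, n = 3). TFF1 fell to 12.18 ± 2.29 CPM and PGR rose to 84.84 ± 14.2 CPM (SD, n = 3).

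By edgeR, 5987 genes were called, 3026 of them higher and 2961 lower, with 142 and 297 at least 2-fold. The libraries did not overlap for 7319 of all genes tested, where chance gives 10%. Scaled by library size alone, 2439 genes rose and 3453 fell, and with RLE size factors 2698 rose and 3241 fell. The largest rises were in GJA1, the gene of connexin 43 (2.27), the protocadherin PCDH9 (2.00), MAPK8IP2 (1.91), IFI44L (1.85), the presynaptic gene BSN (1.79), FSTL5 (1.66), the netrin receptor UNC5C (1.61) and SEMA6A (1.54). GJA1 stood near the detection limit in both groups, at 0.286 ± 0.166 and 1.48 ± 0.636 CPM (SD, n = 3). After SET (-1.96), the largest falls were in the condensin subunit NCAPG (-1.62), FANCB (-1.55), the spindle and kinetochore gene SKA1 (-1.53), NEK2 (-1.50), the securin gene PTTG1 (-1.46), ASPM (-1.44) and CEP55 (-1.44). ESR1 rose by 0.26 (SE 0.04), GREB1 fell by 0.28 (SE 0.04), CCND1 fell by 0.50 (SE 0.04) and MYC fell by 0.34 (SE 0.06).

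All 40 S phase genes fell, with a median of -0.99 (camera adjusted p = 2.12e-86), as did 39 of 40 mitosis genes, with a median of -1.15 (adjusted p = 9.32e-94). Of 25 histone chaperones, 17 fell and 7 rose (adjusted p = 7.66e-18), SET included, with NAP1L1 (-0.85) and SUPT16H (-0.83) among the falls. These 3 lists also passed with an estimated correlation. Interferon-stimulated genes rose in 26 of 34 cases and none fell by edgeR, where IFIT1 had 0.89 and BST2 0.52 (adjusted p = 3.28e-10, and adjusted p = 0.238 with an estimated correlation). Ribosome biogenesis and MYC target genes fell in 12 of 32 cases and rose in 2 (adjusted p = 0.000537, and adjusted p = 0.0733 with an estimated correlation). Cholesterol synthesis genes rose in 11 of 24 cases and fell in 1 (adjusted p = 0.00519, and adjusted p = 0.301 with an estimated correlation). Basal and mesenchymal markers rose in 5 of 14 cases, led by FN1 (1.14) and the integrin ITGA6 (0.46), and none fell by edgeR (adjusted p = 0.00776, and adjusted p = 0.0643 with an estimated correlation). Counted as adjusted over the list alone, 27 interferon-stimulated and 15 ribosome biogenesis genes were called, against 26 and 14 over all genes, with the other counts of this paragraph the same.

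Estrogen receptor and cofactor genes rose in 10 of 27 cases and fell in 6, with the androgen receptor AR (0.52), the arginine methyltransferase CARM1 (0.58) and PGR (0.78) higher. That list's call was at the threshold (adjusted p = 0.0453, and adjusted p = 0.397 with an estimated correlation) and was lost in 11 other settings, with adjusted p from 0.05 to 0.12. The estrogen-induced list gave 16 rises and 19 falls of 54 (adjusted p = 0.687) and the estrogen-repressed list 6 rises and 5 falls of 20 (adjusted p = 0.775). The p53 list gave 12 rises, with CDKN1A at 0.33, and 5 falls of 26 (adjusted p = 0.197). Partners of SET and PP2A gave 5 rises and 5 falls of 21 (adjusted p = 0.0792), where HMGB2 fell by 1.19 and ANP32E fell by 0.99, and where the median was 0.06 and the mean -0.13. The estrogen-repressed list had a median of -0.01 and a mean of -0.09, and camera gave its direction as up. Immediate early genes gave 8 rises and 3 falls of 23 (adjusted p = 0.144), with JUN at 0.86 and EGR1 at 0.80. When adjusted over the list alone, the counts of called genes in the order of this paragraph were 17, 37, 12, 17, 13 and 12, against 16, 35, 11, 17, 10 and 11 over all genes. Under DESeq2, 2006 genes rose and 2473 fell.

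The same knockdown in the presence of E2 lowered proliferation genes again and raised genes of the estrogen-repressed list. TP53INP1, a p53-induced stress gene, stood at 51.37 ± 2.94 CPM with control siRNA and at 104.9 ± 1.79 CPM with SET siRNA (SD, n = 3). TFF1 fell from 349.9 ± 13.6 to 173.6 ± 7.0 CPM and PGR rose from 356.5 ± 9.48 to 555.8 ± 11.9 CPM (SD, n = 3). GJA1 rose from 0.787 ± 0.317 to 32.82 ± 1.89 CPM (SD, n = 3). The mitochondrial transcript MT-CO1 rose from 11210 ± 120.0 to 18390 ± 2460 CPM (SD, n = 3).

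By edgeR, 7138 genes were called, 3325 higher and 3813 lower, with 362 and 139 at least 2-fold. The libraries did not overlap for 8371 of all genes tested, where chance gives 10%. With library size alone as the scaling, 2324 genes rose and 5447 fell. The largest rises were in GJA1 (5.33), IFI44L (3.92), HNRNPA1P41 (3.88), UNC5C (3.11), PCDH9 (2.70), the cadherin CDH18 (2.64), the insulin-like growth factor binding protein IGFBP5 (2.53) and MAP1B (2.27). The largest falls were in SET (-1.95), the 7SL RNA gene RN7SL1 (-1.50), the lipid droplet gene PLIN5 (-1.29), RN7SL2 (-1.22), NCL (-1.16), ARC (-1.10) and the histone gene H4C3 (-1.10). The identifier ENSG00000283029 held the same counts as RN7SL1 in all 12 libraries and is the same signal, and the RN7SL genes are near-identical copies, so their split is uncertain. ESR1 rose by 0.15 (SE 0.04, adjusted p = 0.00111, edgeR), a call that library size alone ended at 0.06 (adjusted p = 0.2). GREB1 fell by 0.23 (SE 0.04) and CCND1 fell by 0.46 (SE 0.04), and MYC had a log2 fold change of -0.01 (SE 0.05, adjusted p = 0.864, edgeR).

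S phase genes fell in 39 of 40 cases, with a median of -0.73 (camera adjusted p = 2.21e-52), and mitosis genes in 39 of 40, with a median of -0.68 (adjusted p = 2.08e-56); BIRC5 (-1.03), TYMS (-0.98) and RRM2 (-0.83) were among them. Ribosome biogenesis and MYC target genes fell in 26 of 32 cases and rose in 1 (adjusted p = 7.67e-10). Histone chaperones, SET included, fell in 17 of 25 cases and rose in 4 (adjusted p = 5.68e-16). SET is the target of the siRNA, and the chaperone list was not tested without it. Partners of SET and PP2A fell in 9 of 21 cases and rose in 1 (adjusted p = 0.000732). Estrogen-repressed genes rose in 14 of 20 cases and fell in 2 (adjusted p = 2.86e-09), with TP53INP1 (1.03), BCL6 (0.97), PNRC1 (0.91) and TXNIP (0.66) as examples. Basal and mesenchymal markers rose in 6 of 14 cases and none fell by edgeR (adjusted p = 3.44e-06), where LAMC2 had 1.91, FN1 had 1.26 and CD44 had 0.46. All 7 lists passed with an estimated correlation. Counted as adjusted over the list alone, 22 chaperones and 28 ribosome biogenesis genes were called, against 21 and 27 over all genes, with the other counts of this paragraph the same.

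Interferon-stimulated genes rose in 29 of 34 cases, with a median of 0.87 (camera adjusted p = 1.37e-20, and adjusted p = 0.0658 with an estimated correlation). Mitochondrially encoded genes rose in 12 of 13 cases, with a median of 0.55 (adjusted p = 1.79e-10, and adjusted p = 0.0658 with an estimated correlation). Mitochondrial counts made up 13.3% to 15.6% of the siSET libraries with E2 and 10.3% to 10.4% of the siCtrl libraries with E2. Estrogen receptor and cofactor genes rose in 17 of 27 cases and fell in 5, with TFAP2A (0.80), AR (0.73) and TFAP2C (0.59) higher (adjusted p = 1.01e-06, and adjusted p = 0.0658 with an estimated correlation). Immediate early genes rose in 10 of 23 cases and fell in 6 (adjusted p = 0.0172, and adjusted p = 0.0523 with an estimated correlation), with JUN (0.79), JUNB (0.71) and KLF4 (0.82) higher. Of 54 estrogen-induced genes, 20 rose and 21 fell (adjusted p = 0.748), with CXCL12 (0.74) and TPBG (0.86) higher and SLC7A5 (-0.63) lower. Adjusted over the list alone, 17 immediate early genes were called in place of 16.

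Both knockdown comparisons use different libraries, so their calls share no controls. Of the genes called in each, 1610 rose in both, where independent lists would give 622, and 1740 fell in both, where independent lists would give 698. The log2 fold changes across the 16169 genes had a Pearson correlation of 0.50 and a Spearman correlation of 0.49, with genes not being independent replicates.

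Estrogen in cells given SET siRNA changed many of the genes that it changed with control siRNA. TFF1 rose 14.2-fold, from 12.18 ± 2.29 to 173.6 ± 7.0 CPM (SD, n = 3), and GREB1 rose 5.96-fold, from 263.0 ± 5.09 to 1569 ± 55.8 CPM (SD, n = 3). PGR rose 6.55-fold and MYC rose 2.62-fold, from 40.44 ± 2.89 to 105.8 ± 1.99 CPM (SD, n = 3). ESR1 fell from 1657 ± 47.9 to 884.2 ± 14.8 CPM (SD, n = 3).

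By edgeR, 9311 genes were called, 4617 higher and 4694 lower, with 847 and 711 at least 2-fold. The libraries did not overlap for 9751 of all genes tested, where chance gives 10%. With library size alone as the scaling, 3680 rose and 5844 fell. The largest rises were in MYBL1 (4.86), EGR3 (4.61), GJA1 (4.46), the apoptosis inhibitor BIRC3 (3.99) and TFF1 (3.83), and the largest falls in CLEC3A (-7.04), FSTL5 (-3.95), FOXI1 (-3.31), WNT2B (-3.12) and IL1R1 (-3.09). Of the genes called, 3475 rose in both siRNA conditions, where independent lists would give 1419, and 3168 fell in both, against 1305. These 2 E2 comparisons share no libraries, and their log2 fold changes had a Pearson correlation of 0.83 and a Spearman correlation of 0.76 across genes.

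The estrogen-induced list gave 47 rises and 3 falls of 54 (camera adjusted p = 3.51e-88) and the estrogen-repressed list 14 falls and 4 rises of 20 (adjusted p = 4.21e-08). All 40 mitosis genes rose, with a median of 2.18 (adjusted p = 3.56e-135), and 39 of 40 S phase genes rose, with a median of 0.90 (adjusted p = 4.65e-25). Ribosome biogenesis and MYC target genes rose in 29 of 32 cases (adjusted p = 1.89e-08), histone chaperones in 17 of 25 with 3 lower (adjusted p = 5.2e-06), and immediate early genes in 14 of 23 with 3 lower (adjusted p = 6.86e-06). Partners of SET and PP2A rose in 10 of 21 cases and fell in 3 (adjusted p = 0.00265), and p53 target genes fell in 15 of 26 and rose in 5 (adjusted p = 0.000601). These lists passed with an estimated correlation too, in the case of SET and PP2A partners at an adjusted p = 0.0484. Unfolded protein response genes rose in 13 of 24 cases and fell in 3 (adjusted p = 0.00537, and adjusted p = 0.0764 with an estimated correlation).

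All 13 mitochondrially encoded genes rose, with a median of 0.44 (adjusted p = 0.000983, and adjusted p = 0.302 with an estimated correlation). Interferon-stimulated genes fell in 30 of 34 cases and rose in 2, with a median of -0.66 (adjusted p = 5.71e-08, and adjusted p = 0.265 with an estimated correlation). Luminal markers rose in 7 and fell in 10 of 18 cases, with a mean of 0.35 and a median of -0.12, where TFF1, AGR2 (1.68) and XBP1 (1.31) were higher and ESR1 (-0.91) lower. Camera called that list as higher (adjusted p = 0.00804, and adjusted p = 0.265 with an estimated correlation), and the call was lost under limma-voom (adjusted p = 0.906) and without the low-count filter (adjusted p = 0.933). When adjusted over the list alone, every list of this comparison had the same count as over all genes.

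The question of the series was whether SET changes the estrogen response, which the difference between both E2 effects tests directly. Of the 7 genes named in every comparison, MYC passed the test of the difference and the other 6 did not: it was 0.13 for TFF1 (SE 0.11, adjusted p = 0.444, edgeR), 0.05 for GREB1 (SE 0.06, adjusted p = 0.576), -0.13 for PGR (SE 0.09, adjusted p = 0.294), 0.04 for CCND1 (SE 0.06, adjusted p = 0.683), -0.11 for ESR1 (SE 0.05, adjusted p = 0.143) and 0.01 for SET (SE 0.06, adjusted p = 0.935). MYC had a larger rise with SET siRNA, by 0.33 (SE 0.08, adjusted p = 0.00141, edgeR). Its E2 levels were alike, at 106.7 ± 4.54 CPM with control siRNA and 105.8 ± 1.99 CPM with SET siRNA (SD, n = 3). The vehicle levels differed, at 51.22 ± 1.33 and 40.44 ± 2.89 CPM (SD, n = 3). EGR3 had a smaller rise, by -1.20 (SE 0.23, adjusted p = 8.89e-05, edgeR). Its vehicle levels were low, at 1.71 ± 0.302 CPM with control siRNA and 3.16 ± 0.877 CPM with SET siRNA (SD, n = 3). With E2 it stood at 97.52 ± 2.27 and 77.4 ± 2.28 CPM (SD, n = 3). TFPI, an inhibitor of coagulation, was repressed less, falling from 42.49 ± 4.33 to 5.08 ± 0.877 CPM with control siRNA and from 47.36 ± 0.432 to 19.32 ± 1.37 CPM with SET siRNA (SD, n = 3).

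In all, 3681 genes had a different E2 effect by edgeR, more positive with SET siRNA for 1823 and more negative for 1858, with 209 and 53 of these at least 2-fold. With library size alone as the scaling, 1359 were more positive and 2646 more negative, and DESeq2 called 1395 and 1061. The largest positive differences were in HNRNPA1P41 (5.09), GJA1 (3.06), IGFBP5 (2.41), IFI44L (2.08) and TFPI (1.74). The largest negative ones were in RN7SL1 (-1.60), RN7SL2 (-1.22), EGR3 and RAMP3 (-1.14). IGFBP5 stood at 19.48 ± 1.35, 10.76 ± 1.04, 21.09 ± 1.08 and 62.24 ± 5.48 CPM (SD, n = 3) in siCtrl vehicle, siCtrl E2, siSET vehicle and siSET E2 libraries.

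Among the lists, the estrogen-induced genes did not pass as a set, with 14 genes more positive and 13 more negative of 54 (camera adjusted p = 0.96), and their median of 0.05 and mean of -0.02 differed in sign. MYBL1 (1.18) and XBP1 (0.52) had larger rises with SET siRNA, and CELSR2 (-0.74) and SLC7A5 (-0.49) smaller ones. Estrogen-repressed genes were more positive in 12 of 20 cases and more negative in 1, with a median of 0.60 (adjusted p = 4.35e-11), including TP53INP1 (0.82), PNRC1 (0.95), CCNG2 (0.69) and BCL6 (0.96). Mitosis genes were more positive in 31 of 40 cases, with a median of 0.47 (adjusted p = 1.05e-22), and S phase genes in 20 of 40, with a median of 0.23 (adjusted p = 2.71e-08), ASPM (0.84) and RRM2 (0.52) among them. These 3 lists passed with an estimated correlation. Counted as adjusted over the list alone, the called genes numbered 30, 14, 37 and 22 for these 4 lists in order, against 27, 13, 31 and 20 over all genes. The knockdown medians of mitosis genes were -1.15 in vehicle and -0.68 in E2, and those of S phase genes -0.99 and -0.73. Both lists thus stayed lower with SET siRNA in E2, by less than in vehicle.

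A further 7 lists passed only with the preset correlation. Cholesterol synthesis genes were more negative in 16 of 24 cases and more positive in 2 (camera adjusted p = 3.61e-08, and adjusted p = 0.0977 with an estimated correlation), including the regulator SREBF2 (-0.44). Ribosome biogenesis and MYC target genes were more negative in 9 of 32 and more positive in 1 (adjusted p = 0.00391, and adjusted p = 0.0977 with an estimated correlation). Interferon-stimulated genes were more positive in 18 of 34 cases (adjusted p = 2.35e-08, and adjusted p = 0.295 with an estimated correlation) and mitochondrially encoded genes in 12 of 13 (adjusted p = 2.97e-12, and adjusted p = 0.0977 with an estimated correlation). Estrogen receptor and cofactor genes were more positive in 14 of 27 and more negative in 4, with NCOA3 at 0.55 (adjusted p = 0.00161, and adjusted p = 0.295 with an estimated correlation). Luminal markers were more positive in 9 of 18 and more negative in 3 (adjusted p = 0.00696, and adjusted p = 0.295 with an estimated correlation). Basal and mesenchymal markers were more positive in 3 of 14 and more negative in 1 (adjusted p = 0.033, and adjusted p = 0.0977 with an estimated correlation), and leaving out siCtrl E2 library B, siSET vehicle library A or siSET E2 library A ended that call, with adjusted p from 0.0507 to 0.0526. Adjusted over the list alone, 20 cholesterol, 11 ribosome biogenesis, 20 interferon and 19 cofactor genes were called, against 18, 10, 18 and 18 over all genes.

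To summarise the E2 response without choosing genes by either arm, gene sets were taken from the average E2 effect over both siRNAs. The median difference was -0.001 over 5460 induced genes (fry adjusted p = 0.611), with 663 weaker and 685 stronger in siSET cells, and 0.017 over 5418 repressed genes (fry adjusted p = 0.0264, camera adjusted p = 0.376), with 798 weaker and 693 stronger. Both medians are small and moved with the scaling: with RLE size factors the induced set had 0.020 and the repressed set 0.038, and with library size alone the induced set had -0.054. Each of these passed an unadjusted fry test at 0.05, and the repressed set with library size alone, at -0.051, did not. Leaving out siSET vehicle library A or C also ended the call on the repressed set, at medians of 0.006 and 0.014. Among genes with at least a 2-fold average effect, 800 repressed genes had medians of -1.58 in siCtrl and -1.25 in siSET cells and a median difference of 0.35 (fry adjusted p = 2.6e-07), with 202 repressed less and 20 repressed more in siSET cells. The 760 genes induced at least 2-fold had a median difference of 0.23 (fry adjusted p = 6.56e-05), with 51 induced less and 185 induced more. Camera called both strong sets, with adjusted p = 1.08e-09 for the repressed and adjusted p = 1.35e-05 for the induced genes, and with adjusted p = 6.88e-05 and adjusted p = 0.0143 with an estimated correlation. The strong sets were chosen after the data were examined.

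**Figure D3:**
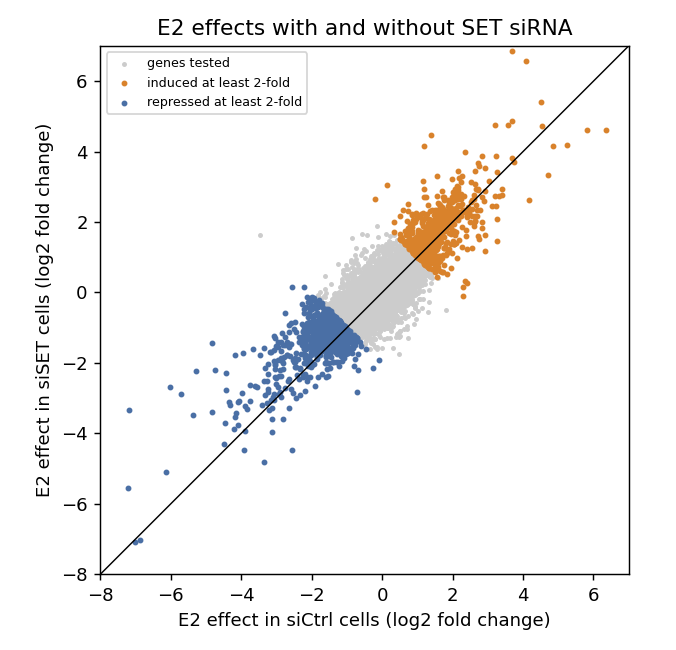
E2 effect in siSET cells (vertical axis, log2 fold change) against E2 effect in siCtrl cells (horizontal axis, log2 fold change) for the 16169 genes tested; the line marks equal effects. Of the 800 genes repressed at least 2-fold on average (blue), 202 were repressed less in siSET cells and 20 more; of the 760 induced at least 2-fold (orange), 51 were induced less and 185 more.

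Across genes, the average SET knockdown effect ran against the average E2 effect, with a Pearson correlation of -0.25 and a Spearman correlation of -0.27 over 16169 genes. Genes raised by E2 and lowered by the knockdown numbered 2311, where independent lists would give 1377, and genes lowered by E2 and raised by the knockdown 1975, against 1310. E2 raised and the knockdown lowered most genes of the S phase and mitosis lists. The estrogen-induced list passed camera in neither knockdown comparison (adjusted p = 0.687 in vehicle and adjusted p = 0.748 in E2). Without the low-count filter the Pearson correlation was 0.036, and with the filter of 1 CPM in 3 libraries it was -0.262.

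**Figure D4:**
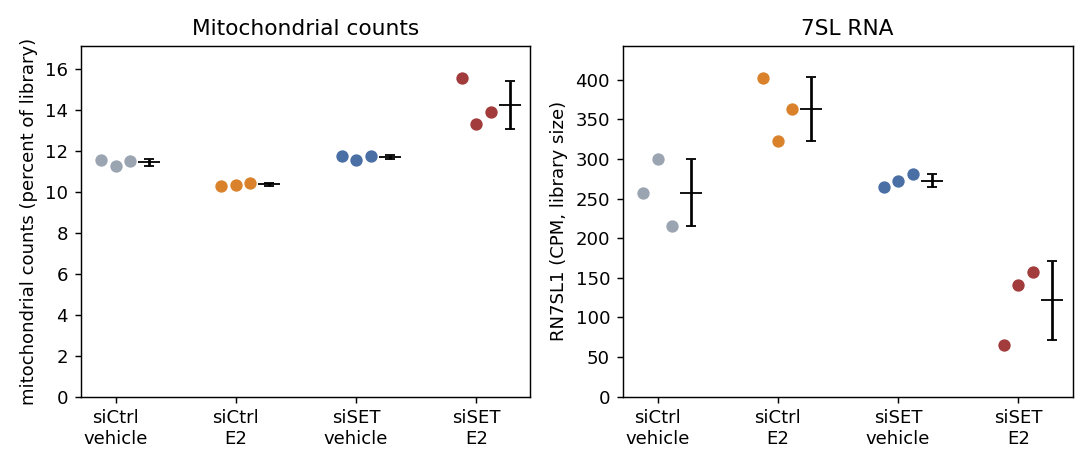
Mitochondrial counts as percent of each library (left) and RN7SL1 in CPM by library size (right) in the 12 libraries, by siRNA and treatment. Points are libraries and the line with bars is the mean with its SD over 3 libraries; the siSET E2 libraries hold 13.3% to 15.6% mitochondrial counts and 64.9 to 157.7 CPM of RN7SL1.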

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

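The scaling and single-library tests of the strong repression and the test without siSET E2 library A were chosen after those results were seen. Results are listed here because the E2 effect differed between siSET and siCtrl cells by a test of the difference itself, which called 3681 genes. When siRNA labels were reassigned within each treatment, 1 of 100 splits, the real one, called as many, and the highest other split called 3070. By construction such splits carry the knockdown effect into the difference. For the count and the sets below they could therefore exclude chance only as the source of any siRNA effect at all, not of the difference itself. For the E2 effect in siCtrl cells, the knockdown in vehicle, the knockdown in E2 and the E2 effect in siSET cells, 1 of 10 splits, the real one, called as many genes (9464, 5987, 7138 and 9311), and the highest other split called 0 by edgeR. At an unadjusted p under 0.05 the highest other split called 381, 764, 569 and 708 genes. With 10 splits a share under 0.05 cannot be reached.

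The lists that passed camera on the difference had medians of 0.604 for estrogen-repressed genes, 0.169 for estrogen receptor and cofactors, 0.234 for S phase genes, 0.466 for mitosis genes, 0.379 for interferon-stimulated genes, -0.256 for cholesterol synthesis genes, -0.125 for ribosome biogenesis and MYC target genes, 0.152 for luminal markers, 0.158 for basal and mesenchymal markers and 0.464 for mitochondrially encoded genes. With an estimated correlation the calls on estrogen-repressed, S phase and mitosis genes held. The other 7 were lost, at an adjusted p = 0.295 for the cofactor, interferon and luminal lists and an adjusted p = 0.0977 for the cholesterol, ribosome biogenesis, basal and mitochondrial lists. Among named genes the difference was 0.327 for MYC, 5.088 for HNRNPA1P41, 3.057 for GJA1, 2.411 for IGFBP5, 2.075 for IFI44L and 1.743 for TFPI. It was -1.603 for RN7SL1 and for ENSG00000283029, which hold identical counts, -1.222 for RN7SL2, -1.198 for EGR3 and -1.143 for RAMP3. The genes induced at least 2-fold had a median difference of 0.228. Of 100 splits, 50 gave a median as far from 0, the highest at 0.585, so they did not exclude chance for that set. Since they carry the knockdown effect, they cannot decide about its difference either.

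The 800 genes repressed at least 2-fold by E2 had a median difference of 0.35, a weaker repression in siSET cells. Of 100 splits, 1, the real one, reached it, with 0.301 as the highest other, which decides nothing about the difference itself. The tables argue against the scaling of the libraries, with a lowest median of 0.284 over 3 other scalings, and against a single library, with a lowest median of 0.311 over the 12 fits with 1 left out. They argue against a trend with expression level, since matched genes without an E2 response had a median of -0.026 over 1000 draws, and against a floor at low counts, since 169 repressed genes with at least 10 CPM in siCtrl E2 libraries had a median of 0.296, with 90 of them called weaker and 11 stronger. An effect of SET loss may be one explanation, as a hypothesis found and tested on the same data. GC content, gene length, E2 exposure, RNA quality and other effects of the siRNA pool stay open. The siSET E2 libraries held 14.3% mitochondrial counts on average against 10.4% in siCtrl E2 libraries, and had TMM factors from 0.93 to 0.965. MALAT1 by library size stood at 34602 to 36049 CPM in siSET E2 and 34214 to 37816 in siSET vehicle libraries. It stood at 16098 to 17176 in siCtrl E2 and 26280 to 27967 in siCtrl vehicle libraries. MALAT1 was therefore lower with E2 in siCtrl libraries, while the ranges of siSET E2 and siSET vehicle libraries overlapped. Its E2 effect thus differed between the siRNAs, and siSET E2 libraries stood above siCtrl E2 libraries. These values do not decide about RNA quality.

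In E2, mitochondrially encoded genes had a median of 0.55 after SET siRNA, a call that was lost with an estimated correlation (adjusted p = 0.0658), and 7SL RNA fell, with RN7SL1 at -1.50. The tables argue against siSET E2 library A as the sole source: without it the mitochondrial median was 0.42 and RN7SL2 was at -1.05 (adjusted p = 2.55e-17). They do not decide whether short structured RNAs had a lower yield in general. The median over 29 such genes was 0.003, but most of these lay near the floor. The most abundant ones went both ways, with RN7SK at 0.61, RPPH1 at 0.27 and RMRP at -0.51, so not all such RNAs fell. An effect of SET on the mitochondrial and 7SL transcripts may be a candidate explanation, as a hypothesis. RNA quality, the handling of the siSET E2 cultures and other effects of the siRNA pool were not tested. They stay open, since the siSET E2 libraries form 1 group.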

How the results depend on the processing

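The replicate block and the fit without both doubtful libraries were chosen after results were seen, and the other settings before the data were examined. Total counts of called genes stayed within 1.5 times in every setting run, with DESeq2 the lowest at 7911, 4479, 5606, 7788 and 2456 for the E2 effect in siCtrl cells, the knockdown in vehicle, the knockdown in E2, the E2 effect in siSET cells and the difference. By direction, DESeq2 moved 2 counts by more than 1.5 times: 2006 genes rose with the knockdown in vehicle, against 3026, and 1061 had a more negative difference, against 1858. DESeq2 was run on all genes with any count and with its own size factors, so its counts also differ in genes and scaling. With RLE size factors in edgeR these 2 counts were 2698 and 1615. With a replicate block by column letter, as in a paired design, the counts were 9464, 5991, 7128, 9322 and 3732. Of 18 same-letter pairs, 0 had a correlation over 0.1, with a range from -0.079 to 0.089. Of 12 libraries, 6 were closest to a library of their own letter. Counting noise between replicates lowers such correlations, so they do not decide about pairing. Without siSET E2 library A and siSET vehicle library B the counts were 9798, 5723, 6632, 8340 and 2859. Over the 12 fits with 1 library left out, they ran from 8695 to 9678, 5093 to 6140, 6316 to 7338, 8621 to 9309 and 3151 to 4047. The median difference over E2-induced genes was 0.02 with RLE size factors and -0.054 with library size alone, against -0.001. Over E2-repressed genes it was -0.051 with library size alone, 0.014 without the low-count filter, 0.006 without siSET vehicle library A, 0.014 without siSET vehicle library C and 0.031 without siSET vehicle library B, against 0.017. It was 0.038 with RLE size factors, 0.034 without both doubtful libraries and 0.027 without mitochondrial, histone and ribosomal RNA genes. By an unadjusted fry test at 0.05 these 3 and the fit without library B passed, and the other 4 printed here for this set did not. The correlation of both average effects was 0.036 without the low-count filter, against -0.25, and ran from -0.256 to -0.211 with 1 library left out. It was -0.262 with the filter of 1 CPM in 3 libraries. The cause of these changes was not tested. The medians and the correlation were not computed for DESeq2. Of the named-gene results, 12 lost a call in at least 1 setting, 6 of them mitochondrial genes, and 3 list calls were lost in at least 1 setting.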

Other observations

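The families and the shared-exon test below were chosen after the data were examined. Clustered protocadherins are cell adhesion proteins encoded in tandem arrays. By the average knockdown effect, 52 of 53 measured genes rose in single-gene tests, with medians of 0.48 over 16 alpha, 0.84 over 15 beta, 0.39 over 12 gamma A, 0.40 over 7 gamma B and 0.38 over 3 gamma C genes. PCDHB16 rose by 1.02 (SE 0.07, adjusted p = 3.27e-17, edgeR), PCDHB11 by 1.24 (SE 0.11) and PCDHB2 by 0.73 (SE 0.05). As families of a common symbol stem, which also count pseudogenes and so hold 18 beta and 9 gamma B members, the alpha, beta, gamma A and gamma B genes passed camera. With an estimated correlation these calls were lost, at an adjusted p = 0.526 for alpha, adjusted p = 0.236 for beta, adjusted p = 0.709 for gamma A and adjusted p = 0.542 for gamma B; the 3 gamma C genes were too few for that test. In vehicle 51 genes rose and in E2 47 rose. The difference in E2 effect was called more negative for 12 of 12 gamma A, 7 of 7 gamma B and 3 of 3 gamma C genes, which share constant exons, and for 5 of 15 beta genes. The 16 alpha genes had a median of 0.08, opposite in sign (camera adjusted p = 0.719).

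Of 218 families of genes with a common symbol stem and at least 8 members, 15 passed camera for the average knockdown effect and 2 passed with an estimated correlation. The MCM family, which holds the replicative helicase subunits and also MCM3AP, fell in 10 of 10 cases (adjusted p = 2.81e-24, and adjusted p = 0.0347 with an estimated correlation). MCM2 to MCM7 and MCM10 are also in the S phase list, so this call is not separate from the fall of that list. The RAD family, with genes of DNA repair, fell in 14 of 17 (adjusted p = 3.6e-06, and adjusted p = 0.0472 with an estimated correlation). Splicing factors of the SRSF family fell in 8 of 11 (adjusted p = 0.0152, and adjusted p = 0.236 with an estimated correlation). For the difference in E2 effect 8 families passed and 0 with an estimated correlation.

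Alpha and gamma protocadherins share constant exons, so their reads are not independent. The tables argue against these exons as the whole source, since beta genes, which share none, had a median of 0.838 with 14 of 15 higher. They argue against the scaling of the libraries, where the lowest median over all clusters was 0.391. They also argue against a trend with expression level. Of 1000 random sets matched on expression, 0 reached the observed median of 0.454, and the highest had 0.129. Those sets hold unrelated genes, so the draws do not measure chance for genes that share reads. An effect of SET loss may be one explanation, as a hypothesis. Reads shared between similar beta genes, GC content, gene length and other effects of the SET siRNA pool stay open.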
